A study of Rattus norvegicus with 15 samples.

How the data were processed

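Gene expression was measured by bulk RNA sequencing of bone from female Sprague-Dawley rats in 15 libraries, 3 in each of the groups Blank, Model, SYT, YJT and YJZYT. Groups and replicate numbers were taken from the sample titles and condition labels. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was selected on oligo(dT) beads and fragmented, the complementary strand was marked with dUTP and removed with UDG, adapters carrying unique molecular identifiers were ligated, and libraries were sequenced as paired ends on an Illumina NovaSeq. Poly(A) selection affects which transcripts are seen. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, with no role or order. The genome build, the annotation release, the counting step, its strand setting and whether reads were reduced to distinct molecules are not given in the sources used here. Overlapping or antisense genes and near-identical copies may therefore share reads.

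The deposited table holds, per the file headers, a whole-number count and an FPKM value for each of 22468 genes in each library, with Ensembl rat gene identifiers, symbols and coordinates. The count values were used as deposited by the authors, and their column totals ran from 64472700 to 74255667. A count of 4 occurred 5143 times against 3519 for a count of 3 and 2314 for 5, while a count of 1 occurred 4679 times against 4353 for 2. The cause of this unevenness is not known here, and single low counts are read with care. The FPKM values were made by the authors, and over 8157 genes with high counts in every library the ratio of count to FPKM, scaled per library, had a median coefficient of variation of 0.019%. A symbol was shared with another entry by 2261 genes, which were kept apart by identifier.

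Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were filtered with filterByExpr (17657 tested, 4811 left out), scaled with TMM factors and fitted in 1 robust quasi-likelihood model of all 15 libraries with a mean per group, which leaves 10 residual degrees of freedom. The biological coefficient of variation was 42.7% and the median prior degrees of freedom 3.05. The 7 contrasts were Model against Blank, SYT, YJT and YJZYT each against Model, and the 3 pairs of these, each two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the root of the F statistic. Shares of counts were compared between groups with exact two-sided permutation tests, for which 3 against 3 libraries cannot give less than 0.1. Single-library shares carry a 95% Wilson interval.

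Before the data were examined, 33 lists of genes were fixed for bone cells, marrow and blood cells, fat, vessels, tendon and fibroblasts, skeletal muscle, nerve, and for signalling, stress and metabolic pathways, together with the tests, the alternatives and the rule for naming genes. Each list was tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. The median of a list's edgeR fold changes and the median of its differences in mean log2 CPM, which camera tests, differed by more than 0.4 for 13 of 103 called lists over the contrasts, and had opposite signs for 0. Single members were counted over all genes and adjusted over the list alone. A list score is the median over its genes of the log2 CPM deviation from the mean of the 15 libraries, with a prior count of 2. Genes were named by this rule: in contrasts with Model, up to 10 genes in each direction past the threshold that carry a symbol, reach a group mean of 1 FPKM and separate all 3 libraries of each group, filled to 5 with the smallest unadjusted p where fewer passed, each then said not to pass. Also named were up to 4 members of each list past the threshold and 12 key genes of bone and fat whatever their p. Members past the threshold adjusted over the list alone were named as examples after their values were seen. In contrasts between SYT, YJT and YJZYT no gene passed, so the rule named none.

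Alternatives fixed beforehand were RLE size factors, no low-count filter, a mean FPKM of at least 5, DESeq2 1.42.0, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes at 1 FPKM in 3 libraries. Others were only the 6 libraries compared, the replicate number as a block, each library left out in turn, and an unadjusted threshold with a 2-fold change. Chosen after seeing the data were the fits without YJT3 and YJZYT3, with the osteoblast and muscle list scores as covariates, and with no scaling factors beyond library totals. Contrasts that share a group were compared with 100 random draws of the libraries into groups after group means were divided out. In counts simulated for Model against Blank over 17315 genes, edgeR recovered 19.4% of 67 genes changed 2-fold, 58.2% of 67 changed 4-fold and 68.2% of 66 changed 8-fold with 2 false calls. DESeq2 recovered 32.8%, 73.1% and 83.3% with 37 false calls. limma on log2 CPM recovered 19.4%, 58.2% and 71.2% with 1 false call. A separate draw of simulated counts, over 17335 genes, was used for the set test of camera. There a list changed 2-fold had an adjusted p of 1.41e-18 with the preset and 5.12e-05 with the estimated correlation, and 0 of 32 unchanged lists were called. Simulated genes were drawn independently, so this run cannot show how either correlation performs on lists whose genes vary together. An exploratory set test over KEGG pathways, made after seeing the data, is not reported here. No genome sequence was used here.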

Results

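Bone from female Sprague-Dawley rats was profiled by bulk poly(A) RNA sequencing in 15 libraries, 3 in each of 5 groups. Blank rats were untreated and not ovariectomized, and Model rats were ovariectomized, which removes the main source of oestrogen and lowers bone mass. SYT, YJT and YJZYT were ovariectomized rats under conditions known here only by these labels. The series concerns Zhuanggu Zhitong Capsule, a Chinese herbal preparation, and the labels do not say which group received it. Libraries are named by group and replicate (Model2 is replicate 2 of Model). Library totals ran from 64472700 to 74255667 counts. Over all tested genes, the correlation of log2 values between libraries had a median of 0.952 over the 15 pairs within groups (0.923 to 0.971) and of 0.947 over the 90 pairs between groups (0.875 to 0.966). No separate animals are named for the replicates, so p-values measure only the spread between these samples, which may be technical. Group values below are TMM-scaled counts relative to the library total (CPM) as mean ± SD with n = 3, fold changes are on the log2 scale with their standard error (SE), and adjusted p-values for genes come from edgeR's quasi-likelihood test. Medians of lists are over edgeR's fold changes of group means, while the set test compares means of log2 CPM, where a single low library weighs more.

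Shares of tissue-specific transcripts varied widely between libraries. Col1a1, which encodes the main collagen chain of bone, took 0.228% of the counts in YJT3 (95% Wilson interval 0.227 to 0.229) and 0.226% in YJZYT3 (0.225 to 0.228), against 7.1% in SYT3 (7.1 to 7.11). These intervals cover counting error only. Acta1, skeletal muscle actin, took 0.168% ± 0.0561 (SD, n = 3) of counts in Blank, 0.0172% ± 0.0129 in Model, 0.0695% ± 0.0413 in SYT, 0.106% ± 0.0128 in YJT and 0.0091% ± 0.0109 in YJZYT. Transcripts of the mitochondrial genome took 8.07% ± 2.38 in Blank, 11.3% ± 1.92 in Model, 18.1% ± 6.58 in SYT, 17.3% ± 5.05 in YJT and 10.4% ± 4.71 in YJZYT (SD, n = 3). Haemoglobin transcripts took 11.7% ± 2.54 in Blank, 7.3% ± 3.21 in Model, 9.45% ± 4.95 in SYT, 10.8% ± 4.09 in YJT and 15.5% ± 6.07 in YJZYT. In exact two-sided permutation tests of the mitochondrial share, p was 0.2 for SYT against Model and 0.3 for YJT against Model, where 3 against 3 libraries cannot give less than 0.1.

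Model against Blank asks which genes differ in bone after ovariectomy. No sham-operated group is described, so surgery and loss of the ovaries cannot be told apart in this contrast. Mlf1, Sh3bgr, Adssl1 and Pkia fell. Mlf1 encodes myeloid leukemia factor 1, Sh3bgr a small protein abundant in heart and skeletal muscle, Adssl1 the muscle form of adenylosuccinate synthase in the purine nucleotide cycle, and Pkia an inhibitor of protein kinase A. Mlf1 (ENSRNOG00000012827) was at 25.6 ± 4.55 CPM in Blank and 4.43 ± 0.632 in Model (log2 fold change -2.53, SE 0.33, edgeR adjusted p = 0.028). Sh3bgr (ENSRNOG00000028238) went from 30.6 ± 4.24 to 5.6 ± 2.16 CPM (-2.45, SE 0.35, edgeR adjusted p = 0.046). Adssl1 (ENSRNOG00000046763) went from 57.7 ± 8.93 to 13.4 ± 2.48 CPM (-2.10, SE 0.28, edgeR adjusted p = 0.029), and Pkia (ENSRNOG00000012095) from 22.6 ± 2.85 to 5.61 ± 1.86 CPM (-2.01, SE 0.26, edgeR adjusted p = 0.028). In the coordinates of the deposited table, whose genome build is not given in the sources used here, Mlf1 lies on chromosome 2 from 164549455 to 164582643, Sh3bgr on chromosome 11 from 36555416 to 36579535, Adssl1 on chromosome 6 from 137184820 to 137206693 and Pkia on chromosome 2 from 96595088 to 96668222. For each of the 4, all 3 Model libraries lay below all 3 Blank libraries. They were the only genes of 17657 tested to pass, while 1446 had an unadjusted p under 0.05 against 882.85 by chance. DESeq2 called 289 genes (62 higher, 227 lower), these 4 among them, and limma on log2(FPKM + 1) called 40, all lower. The edgeR count was 0 without Blank1, without Blank3, without Model1, without Model2, or without both YJT3 and YJZYT3, 1 without Model3 and 5 without Blank2. It was also 0 with the replicate number as a block, with no scaling factors and with bone and muscle scores as covariates.

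**Figure D1:**
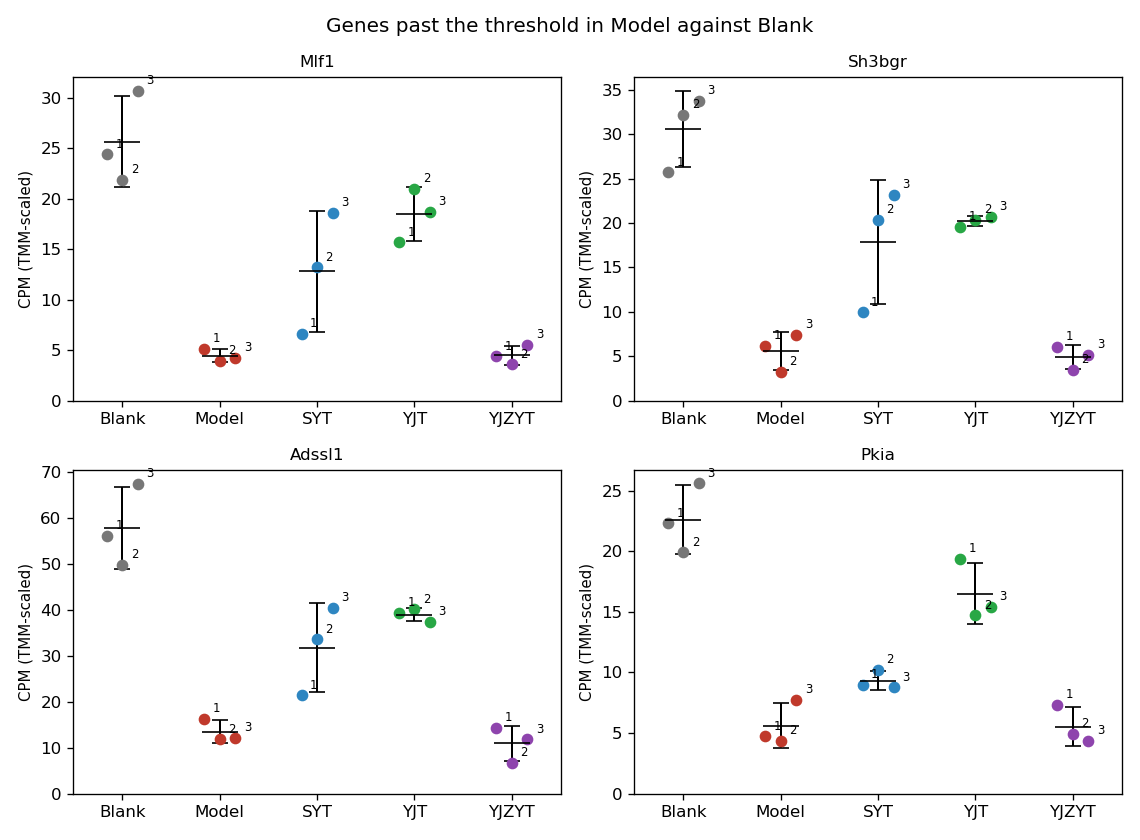
TMM-scaled CPM (vertical axes, linear from 0) of the 4 genes past the threshold in Model against Blank, per library; points are numbered by replicate, horizontal marks are group means and bars are SDs (n = 3). Mlf1 averages 25.6 in Blank, 4.43 in Model, 12.8 in SYT, 18.5 in YJT and 4.49 in YJZYT.

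Skeletal muscle genes were lower in Model as a group. All 17 members of the skeletal muscle list were lower, with a median log2 fold change of -3.01, and 15 of the 17 passed when adjusted over the list alone, none over all genes. Among them were Acta1 (-3.30), Ckm, muscle creatine kinase (-3.56), Mylpf, a fast myosin light chain (-3.05), and Pygm, muscle glycogen phosphorylase (-3.02). The set test gave adjusted p = 1.32e-14 with the preset correlation and adjusted p = 0.509 with an estimated correlation. Fatty acid oxidation genes were also lower, 18 of 18 members, with a median of -0.57 and 11 past the threshold adjusted over the list alone. They included Ucp3, a mitochondrial carrier of muscle (-3.09), Cpt1b, the muscle form of carnitine palmitoyltransferase (-1.48), Pdk4, which restrains pyruvate dehydrogenase (-2.94), and Acadm, an acyl-CoA dehydrogenase (-0.65). That list had adjusted p = 4.95e-13 preset and adjusted p = 0.225 with an estimated correlation.

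Other lists called in Model against Blank involved hormone response, fat and marrow cells. The glucocorticoid response list was lower in 10 of 12 members (median -0.65), with Pdk4, Klf9 (-1.45), Tsc22d3 (-0.92) and Errfi1 (-1.82) past the threshold adjusted over the list alone. The adipocyte list was lower in 15 of 19 (median -0.73), with Fabp4, a fatty acid carrier, at -1.95 as its 1 member past the threshold adjusted over the list alone. Both had adjusted p = 0.509 with an estimated correlation. Erythroid genes were lower in 19 of 19 (median -0.63), megakaryocyte genes in 14 of 14 (-0.83), endothelial genes in 13 of 14 (-0.59) and tendon, periosteum and fibroblast genes in 15 of 18 (-0.44). B cell genes were higher in 20 of 20 (median 0.52) and T and NK cell genes in 17 of 20 (0.67). None of these 6 lists had a member past the threshold adjusted over the list alone, and with an estimated correlation adjusted p = 0.682 for the erythroid list and 0.509 for the other 5. The plasma cell list (median 0.30), the circadian clock list (-0.35, with Per1 at -1.87 adjusted over the list alone) and the glycolysis and hypoxia list (-0.15; Aldoa at -1.23 and Bnip3 at -1.51 adjusted over the list alone) were called too, with adjusted p = 0.509, 0.599 and 0.509 with an estimated correlation. The plasma cell call ended without Blank1, Blank2 or Model3 (adjusted p 0.0508 to 0.147), the circadian call without Blank2, Model1 or Model2 (0.0577 to 0.141), and the glycolysis call without Blank2 or Model3 (0.0746 and 0.253). Model2 carried much of several lists: without it, on the log2 CPM scale, the median went from -0.86 to -0.47 for adipocyte, -0.74 to -0.38 for erythroid, -1.26 to -0.83 for megakaryocyte and 0.43 to 0.26 for B cell genes. In all, 13 of the 33 lists were called in this contrast and 0 with an estimated correlation.

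Genes of bone formation and resorption did not pass the test in Model against Blank. Sost, which encodes the osteocyte Wnt inhibitor sclerostin, was at 14.7 ± 8.03 CPM in Blank and 3.38 ± 2.03 in Model (log2 fold change -2.12, SE 0.86, edgeR adjusted p = 0.53). Tnfsf11, encoding RANKL, had a log2 fold change of -0.73 (SE 0.60) and Tnfrsf11b, encoding its decoy receptor, 0.17 (SE 0.87). The osteoblast genes Col1a1, Bglap, Runx2 and Sp7 had 0.40, 0.29, 0.24 and 0.53, and the osteoclast genes Ctsk and Acp5 had 0.37 and 0.17. Esr1, the oestrogen receptor alpha gene, had 0.95 (SE 0.72), and the fat cell genes Adipoq and Pparg had -1.12 and -0.57. Their edgeR adjusted p-values lay between 0.80 and 0.99. The osteoblast, osteocyte, osteoclast, chondrocyte, Wnt, and BMP and TGF-beta lists had medians of 0.24, 0.08, 0.17, 0.44, 0.05 and -0.23, none called, and the osteocyte and Wnt means had the opposite sign (-0.08 and -0.14). Among genes that also did not pass, the smallest p-values on the higher side belonged to Pigv, a mannosyltransferase of GPI anchor synthesis (0.95, SE 0.19), Fastkd1 (0.87, SE 0.20), Phf8, a histone demethylase (0.55, SE 0.13), Dalrd3 (0.76, SE 0.18) and Skp2, a ubiquitin ligase subunit (0.69, SE 0.16). Their edgeR adjusted p-values ran from 0.20 to 0.28. Pla2g12a, a secreted phospholipase, had -1.33 (SE 0.23, edgeR adjusted p = 0.20). Lists not called in any of the 7 contrasts were osteoclast-regulating cytokines, oestrogen and vitamin D targets, nerve and Schwann cell, NF-kappaB inflammation, cholesterol and fatty acid synthesis, and antioxidant response, with medians here of -0.17, -0.01, -0.15, -0.10, 0.02 and -0.14.

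**Figure D2:**
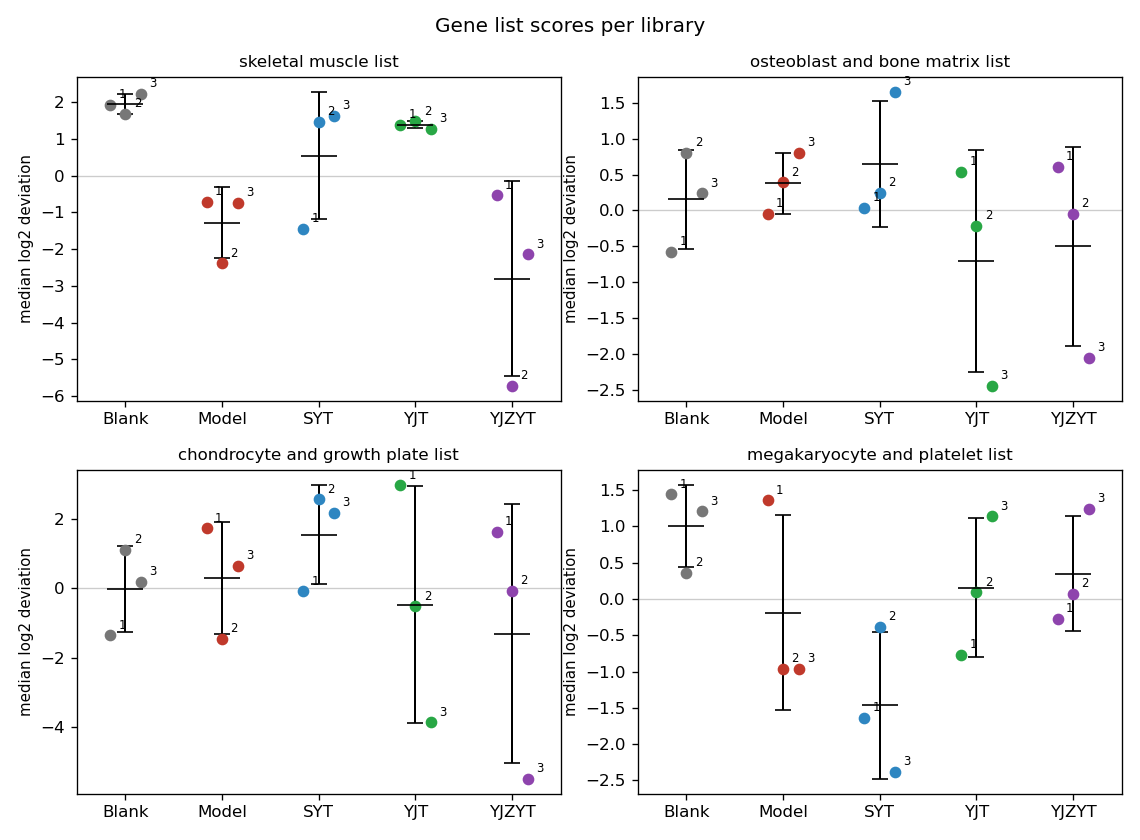
Scores of 4 gene lists per library: the vertical axes give the median log2 deviation of the list's genes from their mean over the 15 libraries, points are numbered by replicate, horizontal marks are group means and bars are SDs (n = 3). The skeletal muscle score is -5.72 in YJZYT2 and the osteoblast score is -2.44 in YJT3 and -2.05 in YJZYT3.

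SYT against Model asks how the ovariectomized rats of this group differ from those of Model. The skeletal muscle list was higher in 17 of 17 members with a median log2 fold change of 2.11, 0 of them past the threshold adjusted over the list alone, and adjusted p = 0.694 with an estimated correlation. The higher values came from SYT2 and SYT3 (list scores 1.46 and 1.63), while SYT1 (-1.45) lay below Model1 (-0.71) and Model3 (-0.74). On the log2 CPM scale the median of 1.61 ran from 1.12 without SYT2 to 2.74 without SYT1. The genes with the smallest p on the higher side were Tnnc1, slow muscle troponin C (73.5 ± 29.8 against 21.6 ± 5.7 CPM, log2 fold change 1.77, SE 0.35), Mlf1 (1.53, SE 0.32), Sh3bgr (1.67, SE 0.35), Adssl1 (1.24, SE 0.28) and Jph1, a protein of muscle membrane junctions (2.10, SE 0.51). Each had an edgeR adjusted p of 1. Unlike the list score, Tnnc1 was highest in SYT1 (104 CPM), with 44.7 in SYT2 and 71.8 in SYT3. Fatty acid oxidation genes were higher in 17 of 18 (median 0.31, or 0.08 without scaling factors, 0 adjusted over the list alone, adjusted p = 0.344 with an estimated correlation). The share of Acta1 was 0.0695% against 0.0172%, and the mitochondrial share 18.1% against 11.3%, with 25.5% in SYT1, 12.9% in SYT2 and 15.9% in SYT3 against 9.17% to 12.9% in the Model libraries.

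The unfolded protein response list was lower in SYT than in Model with the preset correlation, in 11 of 16 members (median -0.26, adjusted p = 0.344 with an estimated correlation). Hsp90b1, a chaperone of the endoplasmic reticulum, was at 376 ± 34.3 CPM against 570 ± 28.4 (log2 fold change -0.60, SE 0.16), and Hspa5, its main Hsp70-type chaperone, had -0.69. These 2 members passed when adjusted over the list alone. Other genes with small p-values on the lower side were Septin7, a cytoskeletal GTPase (75.4 ± 10.5 CPM in Model and 23.8 ± 4.73 in SYT, -1.66, SE 0.33), Klhl17 (-0.96), Parm1 (-0.98) and Hsph1, a heat shock chaperone (-1.16, past the threshold adjusted over the immediate early and handling stress list alone). That list was not called, with a median of 0.04, or -0.19 without scaling factors, and a mean of -0.04. Over all genes their edgeR adjusted p was 1. Low Septin7 was not particular to SYT (24.4, 18.8 and 28.2 CPM): it was at 27.4 CPM in Blank2, against 80.3 in Blank1 and 75.3 in Blank3. Megakaryocyte and platelet genes were lower in 14 of 14 (median -1.50, adjusted p = 0.694 with an estimated correlation), and on the log2 CPM scale the median went from -1.03 to -0.25 without Model1. Further lists were called with the preset correlation: chondrocyte (median 1.14), tendon, periosteum and fibroblast (0.57), erythroid (0.54), circadian clock (0.37), adipocyte (0.23), neutrophil (-0.10), plasma cell (-0.27) and B cell (-0.40), with adjusted p from 0.694 to 0.805 with an estimated correlation. Without scaling factors these medians were 0.93, 0.33, 0.31, 0.14, 0.01, -0.42, -0.53 and -0.64, in that order. The key bone and fat genes did not pass either, with log2 fold changes of 0.39 for Col1a1, -0.18 for Bglap, 0.18 for Runx2, 0.60 for Sp7, -0.94 for Sost, 0.10 for Ctsk, 0.41 for Acp5, -0.19 for Tnfsf11, 1.01 for Tnfrsf11b, -0.35 for Esr1, 0.20 for Adipoq and 0.29 for Pparg. Col1a1 was at 75000 CPM in SYT3, 12900 in SYT1 and 18200 in SYT2, against 27100 ± 14300 in Model. Sp7 was at 52.1 CPM in SYT3, 11.2 in SYT1 and 17.8 in SYT2, against 17.8 ± 7.26 in Model. In the edgeR test 0 of 17657 genes passed, 558 had an unadjusted p under 0.05 against 882.85 by chance, DESeq2 called 27 and limma on log2(FPKM + 1) called 0. Without SYT3 edgeR called 1. List calls ended without Model1 for 3 lists (neutrophil, megakaryocyte, tendon, with adjusted p 0.0571 to 0.108). They ended without Model2 for 9 (chondrocyte, adipocyte, erythroid, neutrophil, B cell, plasma cell, tendon, circadian, unfolded protein response; 0.0644 to 0.992). They also ended without Model3 for the erythroid list (0.109), without SYT1 for the adipocyte list (0.123), without SYT2 for 5 (chondrocyte, adipocyte, erythroid, B cell, plasma cell; 0.241 to 0.333). Without SYT3 they ended for 4 (chondrocyte, neutrophil, tendon, circadian; 0.195 to 0.283). On the log2 CPM scale of the set test, the medians of the adipocyte list (0.35) without Model2 (-0.06), of the erythroid list (0.40) without SYT2 (-0.17) and of the neutrophil list (-0.60) without SYT3 (0.38) turned.

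YJT against Model asks the same of the YJT group. Muscle genes were higher in YJT in 17 of 17 members (median log2 fold change 2.47), and 9 passed when adjusted over the list alone, among them Acta1 (2.78), Mb, the oxygen store myoglobin (2.47), Ckm (2.63) and Tnnt1, slow troponin T (2.73). The set test gave adjusted p = 0.421 with an estimated correlation. The smallest p-values on the higher side belonged to Mlf1 (18.5 ± 2.68 against 4.43 ± 0.632 CPM, 2.06, SE 0.32), Pkia (16.5 ± 2.5 against 5.61 ± 1.86 CPM, 1.56, SE 0.26), Tnnc1 (2.12, SE 0.36), Apold1, an endothelial gene (57.1 ± 7.45 against 27.7 ± 3.04 CPM, 1.04, SE 0.18), and Itgb1bp2, encoding the muscle protein melusin (1.22, SE 0.22). Their edgeR adjusted p-values were 0.17 to 0.24. Fatty acid oxidation genes were higher in 17 of 18 (median 0.45), 8 of them adjusted over the list alone, including Ucp3 (2.41), Pdk4 (2.22), Cpt1b (1.60) and Hadhb (0.55), with adjusted p = 0.421 with an estimated correlation. The share of Acta1 was 0.106% against 0.0172% (exact two-sided permutation p = 0.1, the smallest possible) and the mitochondrial share 17.3% against 11.3%.

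The unfolded protein response list was lower in YJT with the preset correlation, in 11 of 16 members, and 6 of these passed when adjusted over the list alone. They were Pdia4, a protein disulfide isomerase (75.5 ± 8.23 against 130 ± 8.98 CPM, -0.79, SE 0.18), Hspa5 (-0.75), Creld2 (-0.74, SE 0.19), Hsp90b1 (-0.59), Calr (-0.54) and Dnajb9 (-0.54). The list had a median of -0.36 and adjusted p = 0.421 with an estimated correlation. SYT, YJT and YJZYT are compared with the same Model libraries, and without Model2 (score 0.48 against 0.05 and 0.15) this list's call ended in all 3 contrasts. Other lower genes that did not pass were Slc9a9, an endosomal sodium/proton exchanger (-0.91, SE 0.23), Arhgap12 (-0.97, SE 0.25) and Zfp600 (-0.84, SE 0.22), with edgeR adjusted p of 0.67. Bone cell lists were lower: osteocyte genes in 11 of 12 (median -1.31), osteoblast and bone matrix genes in 17 of 19 (-0.77), and osteoclast genes in 17 of 19 (-0.75), with adjusted p = 0.421, 0.746 and 0.543 with an estimated correlation. Tnfsf11 was at 0.818 ± 0.509 CPM against 2.45 ± 0.672 (-1.58, SE 0.61, edgeR adjusted p = 0.75), Ctsk had -1.19, Sost -1.39, Col1a1 -0.97, Bglap -0.92, Sp7 -0.89, Acp5 -0.72, Runx2 -0.58, Tnfrsf11b -0.11, Esr1 -0.15, Adipoq 0.25 and Pparg -0.32, none past the threshold. Col1a1 took 0.228% of counts in YJT3, and without YJT3 the osteoblast call ended (adjusted p = 0.66). On the log2 CPM scale the osteoblast median went from -1.19 to -0.33 and the osteocyte median from -1.37 to -0.89 without YJT3.

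Marrow lists also differed between YJT and Model. Erythroid genes were higher in 19 of 19 (median 0.92, adjusted p = 0.543 with an estimated correlation) and cell cycle genes in 19 of 20 (0.35, 0.793). B cell genes were lower in 20 of 20 (median -0.69), plasma cell genes in 9 of 10 (-0.40), monocyte and macrophage genes in 14 of 16 (-0.62) and marrow stromal genes in 12 of 13 (-0.81), with adjusted p from 0.421 to 0.502 with an estimated correlation. On the log2 CPM scale the erythroid median went from 0.99 to 0.62 without Model2. The marrow stromal median went from -0.87 to -0.53 without YJT3. The Wnt (-0.32), adipocyte (0.54) and circadian clock (0.39) lists were called with the preset correlation, with adjusted p = 0.793, 0.746 and 0.639 with an estimated correlation. In the edgeR test 0 genes passed, 1162 had an unadjusted p under 0.05 against 882.85 by chance, DESeq2 called 96 (87 higher, 9 lower) and limma on log2(FPKM + 1) called 0. List calls ended without Model1 for Wnt (adjusted p = 0.0521), without Model2 for adipocyte (0.701), circadian (0.222) and unfolded protein response (0.0719), without Model3 for Wnt (0.0935) and cell cycle (0.0832), without YJT1 for adipocyte (0.545) and circadian (0.489), without YJT2 for cell cycle (0.138) and without YJT3 for Wnt (0.66) and cell cycle (0.277).

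YJZYT against Model asks the same of the YJZYT group. Red cell and dividing cell genes were higher: erythroid genes in 19 of 19 (median log2 fold change 1.37, adjusted p = 0.59 with an estimated correlation) and cell cycle genes in 20 of 20 (0.61, 0.606), with 0 members of either past the threshold adjusted over the list alone. Haemoglobin transcripts took 15.5% ± 6.07 of counts against 7.3% ± 3.21 in Model (SD, n = 3, exact two-sided permutation p = 0.2). Reads of the haemoglobin genes may be shared between near-identical copies, so values of single members are uncertain. Tendon, periosteum and fibroblast genes were lower in 18 of 18 (median -0.99), with Col3a1, type III collagen (180 ± 90.8 against 690 ± 271 CPM, -1.94, SE 0.48), and Aspn, encoding the matrix protein asporin (-1.98, SE 0.48), past the threshold adjusted over the list alone. The list had adjusted p = 0.596 with an estimated correlation. Aspnl1 (-2.10) has a symbol related to Aspn, and if the copies are near-identical their reads were divided between them in a way not known here. Skeletal muscle genes were lower in 16 of 17 (median -0.73, 0 adjusted over the list alone, adjusted p = 0.642 with an estimated correlation). Without YJZYT2, where Acta1 took 0.000544% of counts (95% Wilson interval 0.000494 to 0.0006), that call ended (adjusted p = 0.851), and the median on the log2 CPM scale of the set test went from -1.45 to -0.08.

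Stress-responsive and glucocorticoid-responsive genes were lower in YJZYT than in Model. Across all libraries these list scores followed the first principal component of log2 CPM, the axis of largest variance (26.7%). Pearson's r with it was 0.74 for immediate early and 0.91 for glucocorticoid genes, and 0.92 for tendon and 0.93 for endothelial genes. A response particular to stress or glucocorticoid genes was not told apart from that shared axis, here or in other contrasts. In the immediate early and handling stress list 16 of 19 members were lower (median -0.64), and 6 passed when adjusted over the list alone. They were Hspa1b, an inducible heat shock gene with a near-identical copy (0.702 ± 0.497 against 5.06 ± 3.11 CPM, -2.85, SE 0.70), Dusp1, a MAP kinase phosphatase (-1.53), the AP-1 genes Fos (-1.14), Jun (-1.07) and Junb (-0.77), and Zfp36 (-0.99). The list had adjusted p = 0.59 with an estimated correlation. In the glucocorticoid response list 10 of 12 were lower (median -0.91), with Tsc22d3, encoding the glucocorticoid-induced leucine zipper (44.3 ± 6.48 against 93.3 ± 5.75 CPM, -1.07, SE 0.24), Errfi1 (-1.62) and Ddit4 (-1.47) past the threshold adjusted over the list alone. Its adjusted p was 0.642 with an estimated correlation. The unfolded protein response list was lower in 12 of 16 (median -0.34): Hspa5 (-0.68), Pdia4 (-0.63) and Hsp90b1 (-0.58) were lower and Asns, asparagine synthetase, was higher (1.28) when adjusted over the list alone. The set test gave adjusted p = 0.59 with an estimated correlation. Interferon response genes were higher in 19 of 21 (median 0.67, adjusted p = 0.642 with an estimated correlation), and YJZYT1 carried this: on the log2 CPM scale the median went from 0.69 to 0.08 without it, and to 0.10 against SYT and 0.06 against YJT. The smallest p-values on the higher side belonged to C1qtnf12, encoding the secreted protein adipolin (1.92, SE 0.32), Mrap, a melanocortin receptor accessory protein (2.05, SE 0.39), Hsd3b7, an enzyme of bile acid synthesis (1.01, SE 0.23), Mmadhc, of vitamin B12 metabolism (0.82, SE 0.19), and Chp1 (1.10, SE 0.26). Each had an edgeR adjusted p of 0.64, as had Tsc22d3, Aspnl1, Aspn, Hspa1b and Col3a1. On the log2 CPM scale the median went from -0.56 to -0.36 for immediate early genes without Model3, from -0.75 to -0.43 for glucocorticoid response genes without Model1 and from -1.16 to -0.67 for tendon, periosteum and fibroblast genes without YJZYT3.

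Bone and stromal lists were lower in YJZYT against Model with the preset correlation: osteoblast (median -0.58), osteocyte (-0.93), chondrocyte (-0.28), Wnt (-0.42), BMP and TGF-beta (-0.68), endothelial (-0.51), marrow stromal (-0.33), monocyte and macrophage (-0.34) and B cell (-0.42). Mast cell, eosinophil and basophil (0.41) and megakaryocyte (0.16, or -0.02 without scaling factors) genes were higher. With an estimated correlation their adjusted p lay between 0.642 and 0.667. Sost had a log2 fold change of 1.29 (SE 0.84), Tnfsf11 -1.32, Tnfrsf11b -1.0, Col1a1 -0.85, Bglap -0.88, Runx2 -0.58, Sp7 -0.31, Ctsk -0.50, Acp5 -0.44, Esr1 -0.31, Adipoq 0.15 and Pparg -0.29, none past the threshold. YJZYT1 carried the Sost value, at 17 CPM against 1.18 in YJZYT2, 6.59 in YJZYT3 and 3.38 ± 2.03 in Model. In the edgeR test 0 genes passed, 1287 had an unadjusted p under 0.05 against 882.85 by chance, DESeq2 called 63 (36 higher, 27 lower), limma on log2(FPKM + 1) called 0, and edgeR called 1 without Model2. Without YJZYT3, where Col1a1 took 0.226% of counts, 10 of the list calls ended (osteoblast, osteocyte, chondrocyte, Wnt, BMP and TGF-beta, monocyte, megakaryocyte, mast cell, endothelial, marrow stromal; adjusted p 0.0859 to 0.661) and the chondrocyte median on the log2 CPM scale turned from -1.57 to 0.58. Calls also ended without Model1 (chondrocyte, BMP and TGF-beta, mast cell, endothelial, marrow stromal, glucocorticoid; 0.05 to 0.281) and without Model2 (B cell, monocyte, megakaryocyte, marrow stromal, unfolded protein response; 0.0642 to 0.438). The same held without Model3 (osteocyte, megakaryocyte, mast cell, endothelial; 0.0536 to 0.769), without YJZYT1 (B cell, marrow stromal, interferon, unfolded protein response; 0.0583 to 0.389) and without YJZYT2 (osteocyte and mast cell; 0.178 and 0.0892).

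SYT, YJT and YJZYT were also compared with each other. In YJZYT against YJT, skeletal muscle genes were lower in 17 of 17 (median log2 fold change -2.84), 15 adjusted over the list alone, among them Acta1 (-3.57) and Myh7, slow myosin heavy chain (-4.44), with adjusted p = 0.188 with an estimated correlation. Tendon, periosteum and fibroblast genes were lower in 18 of 18 (median -1.55), 8 adjusted over the list alone, such as Aspn (-2.94), Col3a1 (-2.22) and Dpt, the matrix protein dermatopontin (-3.74), with adjusted p = 0.188 with an estimated correlation. The immediate early and handling stress list was lower in 14 of 19 (median -0.62; 9 lower adjusted over the list alone, including Fos at -1.56 and Nr4a1 at -1.69). Fatty acid oxidation genes were lower in 18 of 18 (median -0.41, with 4 adjusted over the list alone, including Cpt1b at -2.54). Both lists had adjusted p = 0.188 with an estimated correlation. The glucocorticoid response list was lower in 11 of 12 (median -1.26; 6 adjusted over the list alone, including Pdk4 at -3.37), with adjusted p = 0.3 with an estimated correlation. Other lists called were cell cycle (0.32), erythroid (0.42), interferon (0.48), osteoclast (0.36), B cell (0.28), mast cell (0.31), endothelial (-0.38) and circadian clock (-0.42), with adjusted p from 0.656 to 0.734 with an estimated correlation. Medians on the log2 CPM scale shrank without YJT1 for tendon (-1.58 to -0.79), glucocorticoid (-1.16 to -0.64) and immediate early genes (-0.58 to -0.37), and without YJZYT2 for muscle (-4.16 to -2.52). The Acta1 share was 0.0091% against 0.106% (exact two-sided permutation p = 0.1, the smallest possible). In the edgeR test 0 genes passed (smallest adjusted p = 0.0659), 1128 had an unadjusted p under 0.05, DESeq2 called 388 (12 higher, 376 lower), limma on log2(FPKM + 1) called 87, and edgeR called 74 without YJZYT1 and 2 without YJT3. The smallest p-values included muscle genes, such as Tnnc1 with DESeq2 and limma, and Adssl1 and Cpt1b with edgeR without YJZYT1. Whether muscle carried along with the bone accounts for these calls was not tested. The calls of these other lists ended without YJT1 (erythroid, mast cell, endothelial, cell cycle, circadian; adjusted p 0.132 to 0.458). They also ended without YJT2 (osteoclast; 0.0707), without YJT3 (osteoclast and B cell; 0.364 and 0.598), without YJZYT1 (osteoclast and interferon; 0.471 and 0.204), without YJZYT2 (osteoclast and B cell; 0.0993 and 0.352, the B cell median on the log2 CPM scale turning from 0.25 to -0.01) or without YJZYT3 (erythroid, mast cell, endothelial; 0.0719 to 0.213).

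In YJZYT against SYT, skeletal muscle genes were lower in 17 of 17 (median -2.85; 13 adjusted over the list alone, including Acta1 at -3.02 and Mb at -3.28) and tendon, periosteum and fibroblast genes in 18 of 18 (-1.49; 5 adjusted over the list alone, including Aspn at -2.47 and Col3a1 at -2.51). Glucocorticoid response genes were lower in 10 of 12 (-1.18; Tsc22d3 at -1.30, Ddit4 at -1.95, Errfi1 at -1.55 and Klf9 at -1.38 adjusted over the list alone). Megakaryocyte genes were higher in 14 of 14 (median 1.66; Gp1bb, a platelet receptor subunit, at 4.72 adjusted over the list alone) and cell cycle genes in 20 of 20 (0.63). These 5 lists had adjusted p = 0.449 with an estimated correlation. The muscle median on the log2 CPM scale went from -3.23 to -1.68 without YJZYT2 and the cell cycle median from 0.72 to 0.47 without SYT3. Erythroid (0.80), neutrophil (0.13), mast cell (0.54), interferon (0.53), osteoblast (-0.94), chondrocyte (-1.25), Wnt (-0.58), BMP and TGF-beta (-0.75), endothelial (-0.74), immediate early (-0.45), circadian clock (-0.60) and fatty acid oxidation (-0.43) lists were also called, with adjusted p from 0.449 to 0.535 with an estimated correlation. Without SYT3 the erythroid median on the log2 CPM scale went from 1.13 to 0.58 and the fatty acid oxidation median from -0.43 to -0.28. In the edgeR test 0 genes passed, 1607 had an unadjusted p under 0.05 (510 higher, 1097 lower), DESeq2 called 279 (33 higher, 246 lower) and limma on log2(FPKM + 1) called 0. Calls ended without SYT3 for 7 lists (osteoblast, Wnt, BMP and TGF-beta, neutrophil, mast cell, endothelial, circadian; adjusted p 0.0756 to 0.94), the neutrophil median on the log2 CPM scale turning from 0.71 to -0.36. They also ended without YJZYT1 for interferon (0.293) and without YJZYT3 for 4 (osteoblast, chondrocyte, Wnt, BMP and TGF-beta; 0.0701 to 0.159).

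In YJT against SYT, megakaryocyte genes were higher in 14 of 14 (median 1.52) and osteoclast genes lower in 16 of 19 (-0.81), with 0 members past the threshold adjusted over the list alone and adjusted p = 0.806 with an estimated correlation for every list called. On the log2 CPM scale the osteoclast median went from -0.90 to -0.49 without SYT3, and 13 of the 14 called lists shrank by more than 1.5 times without 1 of the libraries. Osteoblast (-1.08), osteocyte (-1.0), chondrocyte (-0.52), Wnt (-0.44), BMP and TGF-beta (-0.47), B cell (-0.25), monocyte (-0.57) and marrow stromal (-0.54) genes were lower and erythroid (0.34), neutrophil (0.43), cell cycle (0.34) and skeletal muscle (0.32) genes higher, at adjusted p = 0.806 with an estimated correlation. In the edgeR test 0 genes passed, 538 had an unadjusted p under 0.05 against 882.85 by chance, DESeq2 called 8, limma on log2(FPKM + 1) called 0, and edgeR called 1 without YJT1. Calls of these 12 lists ended without SYT1 (B cell, muscle; adjusted p 0.238 and 0.841, the muscle median on the log2 CPM scale turning from 0.80 to -0.13), SYT2 (BMP and TGF-beta, monocyte, marrow stromal; 0.0586 to 0.0629). They ended too without SYT3 (osteocyte, Wnt, BMP and TGF-beta, erythroid, neutrophil, B cell, monocyte, marrow stromal, cell cycle; 0.0517 to 0.922). The same held without YJT1 (muscle; 0.0892), YJT2 (BMP and TGF-beta, erythroid, monocyte, marrow stromal; 0.0726 to 0.323) or YJT3 (osteoblast, osteocyte, chondrocyte, Wnt, BMP and TGF-beta, B cell, marrow stromal; 0.0758 to 0.528).

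The fold changes of SYT, YJT and YJZYT against Model were set against those of Model against Blank, to ask whether values moved back toward Blank. Mlf1, Sh3bgr, Adssl1 and Pkia had the opposite sign in SYT and in YJT, each with an unadjusted p under 0.05, while in YJZYT 1 of the 4 had the opposite sign and none had an unadjusted p under 0.05. These genes were picked as low in Model, the control of these contrasts, so opposite signs can arise without any change in SYT or YJT, and no value without change was made for them. Adssl1 was at 31.8 ± 9.62 CPM in SYT, 39 ± 1.4 in YJT and 10.9 ± 3.87 in YJZYT, and Pkia at 9.31 ± 0.765, 16.5 ± 2.5 and 5.53 ± 1.58. Across 17657 genes, which are not independent replicates, Pearson's r was -0.534 for SYT, -0.611 for YJT and -0.297 for YJZYT. With group means divided out of the counts and the libraries drawn at random into 5 groups of 3, so that no group differs, 100 draws gave a mean r of -0.488 (central 95% from -0.714 to -0.238), since the shared control group enters both contrasts with opposite sign. The covariances were -0.404, -0.518 and -0.251 against a mean of -0.37 in the simulation (central 95% from -0.757 to -0.137). Simulated covariances were scaled up for the degrees of freedom lost when group means were divided out.

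Between these 3 groups, the fold changes against Model correlated at r = 0.575 for SYT and YJT, 0.402 for YJT and YJZYT and 0.297 for SYT and YJZYT. The same random draws gave a mean of 0.51 (0.299 to 0.757), so the value of SYT and YJZYT lay just below that range. With 1 library left out it ran from 0.18 to 0.50, for which no random draws were made. Covariances were 0.418, 0.327 and 0.215 against a simulated 0.385, scaled up in the same way. No gene was called in any of the 3 groups against Model by edgeR (at an unadjusted p under 0.05 the numbers were 558, 1162 and 1287), so calls could not overlap, and the 3 Model libraries are too few to split, so part of any excess may come from the shared controls.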

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

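The fits without YJT3 and YJZYT3, with bone and muscle scores as covariates and with no scaling factors were chosen after seeing the data. In numbers of genes past the threshold, DESeq2 gave 289, 27, 96, 63, 8, 279 and 388 for Model vs Blank, SYT vs Model, YJT vs Model, YJZYT vs Model, YJT vs SYT, YJZYT vs SYT and YJZYT vs YJT, where edgeR gave 4 and then 0 in each. An unadjusted p under 0.05 with a 2-fold change gave 687, 324, 597, 506, 270, 899 and 792. limma on log2(FPKM + 1) gave 40 for Model vs Blank and 87 for YJZYT vs YJT, and on log2(FPKM + 0.1) it gave 2 and 3. For Model vs Blank the count was 8 with only the 6 libraries compared (2 of the 4 genes shared), and 0 with the replicate block, with no scaling factors, with covariates, and without YJT3 and YJZYT3. The muscle score comes from genes of the same tissue as the called ones, so the covariate fit is circular for them. Leaving out 1 library in turn gave 0 to 5 for Model vs Blank, 0 to 1 for SYT vs Model, YJZYT vs Model and YJT vs SYT, and 0 to 74 for YJZYT vs YJT. RLE factors and the absence of a low-count filter kept all 4 genes called, and a mean FPKM of at least 5 kept 3. Over 17 alternatives Mlf1 and Pkia passed in 8, Adssl1 in 7 and Sh3bgr in 4, always with a log2 fold change below 0. Their log2 fold changes ran from -2.71 to -1.93, -2.36 to -1.70, -2.33 to -1.37 and -2.75 to -1.70, in that order. The replicate numbers do not pair the samples: 9 of 30 same-number pairs had a correlation of deviations over 0.1 (-0.42 to 0.40), and 19 of 60 best matches shared the number. The block changed the count of genes in no other contrast. With no scaling factors the median log2 fold change of all genes was -0.22 in SYT vs Model, -0.16 in YJT vs Model and -0.215 in YJZYT vs Model, and with log2(FPKM + 1) it was -0.21, -0.14 and -0.15, so changes in all 3 are relative to the TMM scaling. Of 1460 pairs of a named gene and an alternative, 1386 stayed on the same side of the threshold, 41 lost and 33 gained significance and 0 called values turned. Of the 1386, 1359 were past it in neither fit, and 70 of these had the opposite sign.

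For relations to Model vs Blank, r ran from -0.71 to -0.49 for YJT and from -0.51 to -0.20 for YJZYT with 1 library left out. The YJZYT value was -0.19 with a mean FPKM of at least 5, -0.20 with limma on log2(FPKM + 1) and -0.16 on log2(FPKM + 0.1), settings for which no random draws were made. For SYT and YJZYT r was 0.40 with no low-count filter, 0.32 without YJT3 and YJZYT3 and 0.18 to 0.50 with 1 library left out, and for YJT and YJZYT 0.29 to 0.59. With an estimated correlation 0 lists were called in each contrast, where the preset gave 13, 12, 15, 19, 14, 17 and 13; without YJT3 and YJZYT3 it gave 9 for YJZYT vs Model and 7 for YJT vs SYT. In YJZYT vs Model the replicate block gave 17 lists, without the osteocyte and mast cell calls, and camera on log2(FPKM + 1) gave 21, without the chondrocyte and marrow stromal calls. On that scale the neutrophil call in SYT vs Model and the Wnt call in YJT vs Model also ended. With 1 library left out the preset gave 3 to 16 for SYT vs Model, 9 to 19 for YJZYT vs Model, 6 to 15 for YJT vs SYT and 10 to 19 for YJZYT vs SYT. List medians here are of differences in mean log2 CPM, the scale of the set test. For 79 of 103 called lists the median shrank by more than 1.5 times, or turned, without 1 of the libraries. That of the chondrocyte and growth plate list in YJZYT vs Model turned from -1.57 to 0.58 without YJT3 and YJZYT3, with YJZYT3 alone left out to 0.58 (-3.16 without YJZYT replicate 1). That of the skeletal muscle list in YJZYT vs Model went from -1.45 to -0.0761 without YJZYT2, where the test's direction turned, and to -2.66 without YJZYT replicate 1. In SYT vs Model the adipocyte list went from 0.35 to -0.0603 without Model2 (0.62 without SYT3), the erythroid list from 0.40 to -0.17 without SYT2 (0.93 without SYT3) and the neutrophil granulocyte list from -0.60 to 0.38 without SYT3 (-1.29 without SYT replicate 1). In YJT vs SYT the muscle list went from 0.80 to -0.13 without SYT1 and to 1.41 without SYT2. The cause was not tested.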

Other observations

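The tests of skeletal muscle, bone and marrow content, library size and scaling factors, and of the muscle score between Model and Blank, were chosen after the result was seen. So were the medians and ratios with 1 library left out. Those of the respiratory chain as a whole, of genes at 0 counts and of other splits of the libraries were not. Genes of oxidative phosphorylation split by genome. The 13 tested mitochondrially encoded subunits had a median log2 fold change of 0.94 in SYT against Model and 0.78 in YJT against Model, higher in 13 of 13, while 119 nuclear genes had medians of 0.16 and 0.02. The nuclear set was every tested nuclear gene of the KEGG pathway of oxidative phosphorylation. It was not limited to subunits of the same complexes. With 1 library left out the mitochondrial medians ran from 0.53 (without SYT1) to 1.15 (without SYT2) in SYT and from 0.62 (without YJT2) to 1.0 (without YJT3) in YJT, and the nuclear ones reached 0.31 and 0.20 without Model2. In YJZYT against Model the medians were 0.00 and 0.10, the mitochondrial one running from -0.42 (without YJZYT1) to 0.22 (without YJZYT2). In Model against Blank they were 0.42 (13 of 13 higher, 0.14 without Blank1 to 0.74 without Blank2) and -0.19 (34 of 119 higher). The split itself was not tested in any contrast. The nuclear genes were higher in 104 of 119 in SYT and in 63 of 119 in YJT. These numbers are relative to the TMM scaling. Without scaling factors the median of all genes went from 0.023 to -0.22 in SYT and from -0.016 to -0.16 in YJT. Both shifts are larger than the nuclear medians, for which no value without scaling was made.

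Tldc2 and Stfa2l1 had 0 counts in all 3 Blank libraries, Cdkl4 in Model, Dcx, a microtubule protein of migrating neurons, in YJZYT, and the unnamed gene AABR07050652 in SYT, each with at least 4 counts in the other 12 libraries. They were chosen after their values were seen, and a count of 0 allows up to 3 counts. Stfa2l1 ran from 4 to 660 counts in the other libraries. Random groupings of the 15 libraries held as many such genes in 8 of 100 draws, with a median of 2 and a highest of 18, so these genes may be chance.

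Lower skeletal muscle transcripts in Model than in Blank went with the called genes Mlf1, Sh3bgr, Adssl1 and Pkia. A candidate explanation is muscle carried along with the bone in amounts that differ between samples: with group means taken out, the mean of the 4 genes followed the muscle score over 15 libraries (Pearson r = 0.909, permutation p = 0.000257, adjusted over 4 relations 0.000772; Spearman's rho = 0.929, permutation p = 0.000643; r = 0.962 without YJZYT2 and YJZYT1). Library size argues against itself as a cause, since the mean total of Model was 0.986 of that of Blank. A response of muscle genes to ovariectomy cannot be told apart. The muscle score gave an exact two-sided permutation p of 0.1 for Model against Blank, the smallest for 3 against 3. Carried-along muscle and a response would both lower the score in Model, so this test could not separate them at any p. The within-group correlation would also arise if these genes were regulated together inside muscle, so the amount of tissue is a hypothesis.

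Low bone lists in YJT3 and YJZYT3 (osteoblast scores differing by -2.61 and -2.33 from the other libraries of their group) were weighed against marrow content. More marrow cells of every kind cannot be told apart, as the B cell and T and NK cell lists were lower in both libraries (highest of 4 differences -0.471) but the T and NK cell difference lay within its spread of 0.569 for YJT3. A link with 6 blood and marrow lists together was tried first (Pearson r = -0.646, permutation p = 0.00167, rho = -0.682, r = -0.629 without SYT3 and Model1) and then divided after that result was seen; for erythroid, granulocyte and megakaryocyte cells, 3 lists picked then, r was -0.795 (permutation p = 0.000386, rho = -0.796). Less hard bone with more of these cells cannot be told apart, since the lists were picked on the same libraries and neither this value nor that over the 13 libraries other than the pair (r = -0.872) gives separate support. Library size and scaling do not account for it, with the lower total at 0.949 of the median and the larger TMM factor at 0.111 on the log2 scale. Beyond marrow content no biological explanation was tested, and the libraries come from different groups.

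The mitochondrial share of counts, higher on average in SYT and YJT than in Model though not past its exact test, did not follow skeletal muscle. With group means taken out, its correlation with the muscle score was r = -0.00257 over 15 libraries (permutation p = 0.996, rho = -0.0964, permutation p = 0.83). Without YJZYT2 and YJZYT1, r was -0.648. Neither value shows the rise that more muscle predicts, which argues against more muscle as the cause. The r over 15 libraries is too imprecise to exclude it. Blank, with more Acta1 (0.168%) than SYT (0.0695%) or YJT (0.106%), had a mitochondrial share of 8.07% against 11.3% in Model. A rise of the whole respiratory chain cannot be told apart: the nuclear medians averaged 0.105 of the mitochondrial ones, but 0.297 without Model2, past the bound of a ratio under 0.2. An effect of the conditions SYT and YJT on mitochondrial transcripts stays open and untested.

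The 6 libraries of a contrast allow 10 splits into 3 and 3, too few for a share under 0.05. As many genes as in the real split came in 1 of 10 for Model against Blank (real 4, highest other 0) and in 10 of 10 for the other contrasts, where the real value was 0 by edgeR (558, 1162, 1287, 538, 1607 and 1128 genes had an unadjusted p under 0.05 in the fit of 15 libraries, and DESeq2 called 27, 96, 63, 8, 279 and 388). The highest other value was 1 for SYT against Model, 0 for YJT against Model, 42 for YJZYT against Model, 4 for YJT against SYT, 0 for YJZYT against SYT and 0 for YJZYT against YJT. The 42 came from YJZYT1, Model1 and Model3 against the rest, a split that also parts the muscle scores (-0.54, -0.71 and -0.74 against -2.39, -5.72 and -2.14), which was seen afterwards and not tested.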
